A study of Homo sapiens with 6 samples.

How the data were processed

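Poly(A) RNA from H1792 cells was made into libraries with the Illumina TruSeq mRNA kit, version 2, per the labels' protocols, and 1 library was sequenced for each of 3 shNT and 3 shPHF20 samples. That kit does not mark strand. The same protocol text assigns its 2 sequencing platforms to leukaemia cell lines and not to H1792, so the platform and read layout of these libraries are unclear. The authors deposited raw counts per gene symbol, 1 file per library. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.0 and the genome build hg19. The role of each tool, the annotation, the strand setting, the read length and the treatment of reads that match several places are not given in the sources used here. The files list 25370 genes, none of them mitochondrially encoded, and no summary lines. A ribosomal RNA precursor entry, RNA45S5, was kept as a gene and took 0.354% to 0.936% of each library's counts.

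Samples were grouped by the vector given in the labels. Library totals were 45923400 to 57942900 counts, and the 20 most abundant genes took 7.66% to 9.30% of them. No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom over genes with at least 20 counts was 38.8 to 111, so all 6 were used as separate libraries.

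Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 19941 genes with a count, filterByExpr kept 14628. Libraries were scaled by TMM (trimmed mean of M values), and a quasi-likelihood F test (glmQLFit with robust=TRUE, glmQLFTest) compared shPHF20 with shNT with group as the only term. The p-values are two-sided and were adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Values in CPM are counts relative to the TMM-scaled library total, computed here from the deposited counts, and are given as mean ± SD of 3 libraries. The common biological coefficient of variation was 0.18. For a gene with 1 to 3 counts in a group, a ratio of summed counts with a 95% exact binomial interval is given, which covers counting error only.

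The rule for named genes, the 32 gene lists and the main tests of genes and lists were fixed before the data were examined. Some later checks were chosen after the results were seen, as stated where they are given. The rule names PHF20, PHF20L1 and KAT8 among others, and the 10 genes with the largest rise and the 10 with the largest fall among those called, with a mean of at least 5 CPM in the higher group and no overlap between groups. It adds the called members with the smallest adjusted p of each list, up to 4 for a list past the threshold and up to 2 for any other. It took 101 genes, some of which are not reported here. Lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided and adjusted over the 31 lists with at least 3 tested genes. The list of mitochondrially encoded mRNAs had no gene in the files. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation camera tests on the residual degrees of freedom of the libraries, and with the preset on those of the genes. The estimated setting therefore has less power with 6 libraries, whatever the correlation. Of the 31 lists, 10 passed the threshold with the preset correlation, 6 up and 4 down, and 0 did so with an estimated correlation (1 list, the mesenchymal genes, had an unadjusted p under 0.05 there, at 0.00317). fry called 13 in 1 direction and 31 in either. Mitosis and G2/M, called by camera with the preset correlation, was not among the 13 (fry adjusted p = 0.128). The NSL (0.0255), MLL/SET1 (0.0385), cell death (0.0385) and endothelial (0.0488) lists, not called by camera, were. With the replicate number as a block fry called 6 in 1 direction. They were the NRF2, epithelial and mesenchymal lists, which were among the 13, and the hypoxia, YAP/TEAD and lung lineage lists, which were not. Among those lost were DNA replication, NF-κB, p53 target, integrated stress response, autophagy and lysosomal genes (adjusted p = 0.0859 to 0.105 with the block). The block leaves fewer residual degrees of freedom, on which fry tests, so these losses do not show that pairing removed the differences. Marker genes above 1 CPM were counted on CPM of the unscaled library totals. Older symbols in the files were matched to current ones through a fixed alias table.

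The sample titles give replicate numbers 1 to 3 in both groups but do not say what a number shares. The numbers were taken to pair the libraries because the same-numbered libraries deviated together from their group means: the correlations across genes were 0.23, 0.62 and 0.58 for replicates 1, 2 and 3. The fit with the replicate number as a block, fixed in advance as an alternative, is therefore given beside the unpaired test.

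Gene GC content, transcript length, chromosome, 3' UTR sequence and exon overlap were taken by symbol from GENCODE version 29 on GRCh38, which is not the build the authors used, so no coordinates are given. The largest overlap of a named gene with exons of another gene model is given beside it where it reached 10% of its exonic bases, a bound set after the overlaps were seen, and such values are uncertain since the counting is not stated to use strand. Smaller overlaps, up to 9.85% (RPL31), are not given. Of the tested genes, 14157 (96.8%) were matched and 12691 (86.8%) had a 3' UTR of at least 50 bases. All 7-mers in at least 100 of these 3' UTRs (15730) were scored against the log2 fold changes, limited to between -3 and 3, after a regression on 3' UTR length and GC content, and scores were compared with 100 shuffles within deciles of 3' UTR length. GC content and length were also removed from each library with smooth trends fitted by mgcv 1.9.3 and passed to edgeR as offsets. The 7-mer scan and the figures used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

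The scripts were tested on simulated counts drawn from these libraries' means, sizes and dispersions, with 200 genes changed among 14628. That is fewer than the 6103 called in the data, so the recovery and false-call shares need not hold for the data. For shPHF20 against shNT edgeR recovered 14 of 67 genes changed 1.5-fold (20.9%), 53 of 67 changed 2-fold (79.1%) and 64 of 66 changed 4-fold (97.0%), and 13 calls (9.03%) were false. DESeq2 1.42.0 made 54 false calls (27.1%) and limma-voom 10 (7.46%). With 1 list lowered by 0.5 on the log2 scale, camera called that list and 0 of 30 unchanged lists, both with the preset and with an estimated correlation. Simulated genes were drawn independently, so this could not show whether the preset gives false list calls where members are correlated. In the data the estimated correlation of the 10 lists called ran from 0.00759 (mesenchymal genes) to 0.870 (mitosis and G2/M). In the 7-mer scan over 12691 genes, a planted lowering of 0.3 was recovered as the lowest score and 1 of 0.1 was not.

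The alternatives fixed in advance were the replicate block, DESeq2, limma-voom, DESeq2 size factors (RLE) in edgeR, upper-quartile scaling, library size only, no expression filter, a filter of 1 CPM in 3 libraries, robust=FALSE, each library left out in turn, the 20 most abundant genes removed, a test against a fold of 1.5, and the other list tests. Their effects are given in the closing section.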

Results

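Messenger RNA was sequenced from H1792 cells, an established human lung cancer cell line, after lentiviral delivery of a short hairpin RNA. The pLKO vector carried either a hairpin against PHF20 (shPHF20, 3 libraries) or a non-targeting hairpin (shNT, 3 libraries), and transduced cells were kept under puromycin for 4 to 6 days before RNA was collected. PHF20 is a chromatin reader protein and a subunit of the NSL complex, in which KAT8 acetylates lysine 16 of histone H4. The question asked of these libraries was which transcripts differed once PHF20 was depleted. Total counts ranged from 45923400 to 57942900 per library, and 17615 to 17997 of the 25370 listed genes had at least 1 count. Libraries correlated at r = 0.980 to 0.991 within a group and at r = 0.938 to 0.960 between groups, across genes on the log2 CPM scale. The first principal component held 70.8% of the variance and separated shPHF20 from shNT, and the second held 16.5% and separated the libraries numbered 2 and 3 in both groups. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

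PHF20 transcript was lower in all 3 shPHF20 libraries. Its counts were 6147, 5642 and 7682 in shNT and 1278, 1389 and 1254 in shPHF20, or 117 ± 11.2 and 27.4 ± 1.96 CPM (mean ± SD, n = 3 each). The log2 fold change was -2.10 ± 0.12 (SE, edgeR quasi-likelihood adjusted p = 5.71e-05), which left 23.4% of the shNT mean, and 21.5% to 24.6% in single libraries. The paralog PHF20L1 stood at 55.3 ± 3.98 CPM in shNT and 62.3 ± 8.32 in shPHF20, a difference that did not pass the test (log2 fold change 0.17 ± 0.12, edgeR adjusted p = 0.292). KAT8 fell from 17.9 ± 0.929 to 11.2 ± 0.684 CPM (-0.67 ± 0.12, edgeR adjusted p = 0.00336). Of the 8 other NSL subunits measured, 4 fell and none rose, the same 4 when p was adjusted over the list alone. HCFC1 fell by 0.55 on the log2 scale, from 169 ± 9.64 to 115 ± 7.57 CPM, and the remaining 2, WDR5 at -0.50 and MCRS1 at -0.32, are named here after their values were seen. As a group the NSL subunits were not called against all other genes (camera adjusted p = 0.416). The test fry called them down without a block (adjusted p = 0.0255) but not with the replicate block (adjusted p = 0.105). Of the 3 subunits of the MSL complex, another KAT8-containing complex, MSL1 rose from 33.8 ± 3.58 to 49.7 ± 2.68 CPM and MSL3 fell from 100.7 ± 3.68 to 66.6 ± 11.3 CPM. MSL2, named here after its value was seen, fell by 0.49 on the log2 scale. The same 3 were called over the list alone, and the list was not called (camera adjusted p = 0.693).

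**Figure D1:**
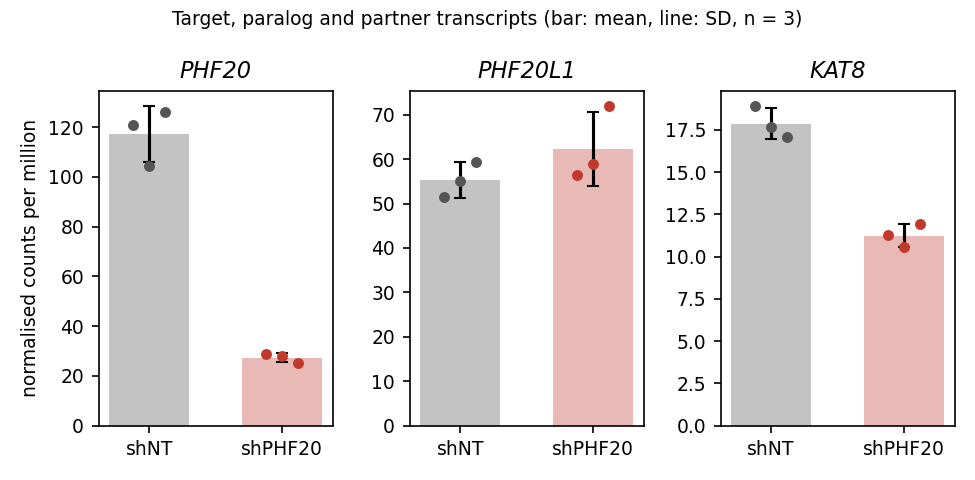
Normalised counts in CPM (y axis) of PHF20, PHF20L1 and KAT8 in shNT and shPHF20 (x axis). Points are libraries, bars the mean and lines the SD of 3 libraries per group, and the 3 shPHF20 libraries lie between 25.2 and 28.8 CPM for PHF20 and the 3 shNT libraries between 105 and 126 CPM.

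Of 14628 genes tested, 6103 (41.7%) differed between shPHF20 and shNT at an edgeR adjusted p under 0.05, 2942 of them higher and 3161 lower. Of these, 1022 higher and 1115 lower genes changed more than 2-fold, and 316 and 180 more than 4-fold. In 7895 genes (54.0%) the values of the 2 groups did not overlap, against the 10% that chance gives for 3 against 3. The median log2 fold change of all tested genes was -0.01. Tested against a change of 1.5-fold instead of none, 1873 genes passed, 891 higher and 982 lower. With the replicate number as a block, a paired design, 8493 passed, 4099 higher and 4394 lower. The 1932 genes whose 3' UTR held the 7 bases ACACCTG, the 7-mer with the lowest z of all 7-mers scored after a regression on 3' UTR length and GC content, had a mean log2 fold change of -0.15, and its presence is given beside the named genes. The 3' UTR of PHF20 held it too.

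**Figure D2:**
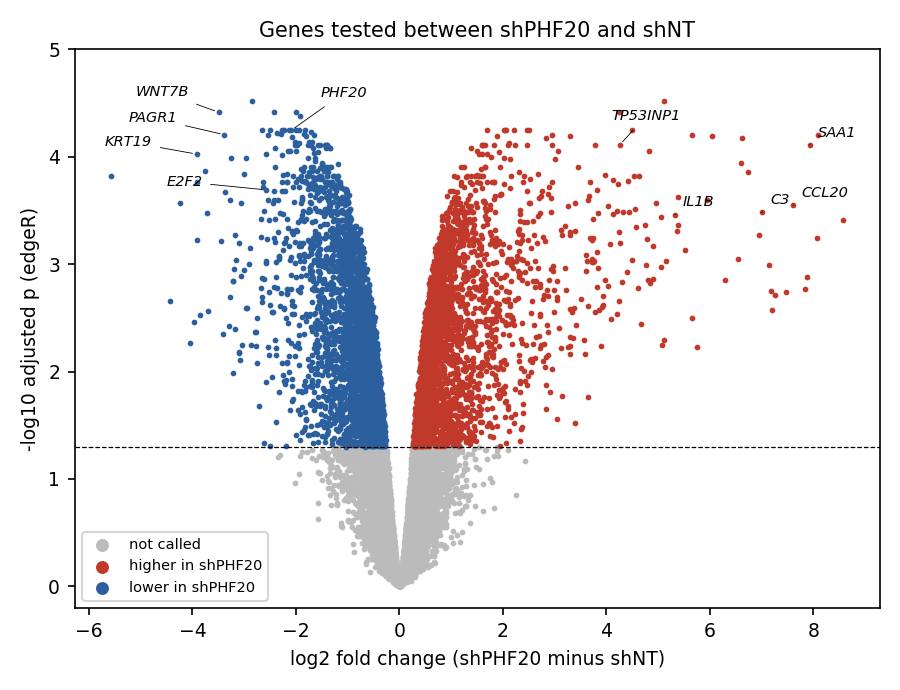
Each point is a tested gene, with the log2 fold change of shPHF20 minus shNT on the x axis and -log10 of the edgeR adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, and red points are the 2942 higher and blue points the 3161 lower genes.

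Among the 10 called genes with the largest rise, at least 5 CPM in the higher group and no overlap between groups, serum amyloid A1 (SAA1) rose from 0.120 ± 0.0880 to 30.003 ± 12.1 CPM and the chemokine CCL20 from 0.314 ± 0.226 to 59.96 ± 39.4 CPM. Complement component C3 rose from 1.56 ± 1.44 to 198 ± 84.3 CPM, a log2 fold change of 7.003 ± 0.721 (SE, edgeR adjusted p = 0.00033). The cytokine IL24 rose from 0.162 ± 0.101 to 15.7 ± 4.54 CPM and the activin subunit gene INHBA from 0.646 ± 0.431 to 30.2 ± 18.8 CPM. SAA2 had 3 counts over the shNT libraries and 794 over the shPHF20 libraries, a ratio of 306 with a 95% exact counting interval of 104 to 1487. SAA1 and SAA2 are near-identical, so how their reads were split is uncertain, and the interval covers counting error only. In the annotation used here, 11.99% of the exonic bases of SAA2 belong to another gene model as well. The lectin-like receptor gene OLR1 reached 8.63 ± 9.34 CPM from 0.0532 ± 0.0321, C15orf48 reached 66.02 ± 17.2 from 1.01 ± 0.434, and FER1L6 reached 32.6 ± 13.2 from 0.642 ± 0.118. Of the exonic bases of C15orf48, 17.1% lie opposite exons of another gene model, so its value is uncertain. SLN, which encodes the calcium pump regulator sarcolipin, rose from 0.155 ± 0.0723 to 7.95 ± 9.52 CPM. A single library moved the fold of several of these genes by more than 1.5 times, with the calls kept: without shNT replicate 1 the log2 fold change was 8.36 for CCL20 (7.61 with all), 7.99 for C3 (7.003 with all) and 7.22 for IL24 (6.61 with all), and the SAA2 ratio was 637 (114 to 25172). Without shNT replicate 3 it was 6.13 for INHBA (5.52 with all), without shPHF20 replicate 3 it was 5.89 for OLR1 (7.25 with all), and without shPHF20 replicate 2 it was 3.95 for SLN (5.65 with all).

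Among the 10 genes with the largest fall by the same criteria was keratin 19 (KRT19), which fell from 33.1 ± 5.33 to 2.17 ± 0.809 CPM (log2 fold change -3.92 ± 0.28, edgeR adjusted p = 9.47e-05). The aldehyde dehydrogenase gene ALDH3A1 fell from 8.41 ± 0.425 to 0.551 ± 0.284 CPM, the splicing regulator gene MBNL3 from 15.4 ± 5.06 to 1.03 ± 0.641, and SFN, which encodes 14-3-3 sigma, from 10.6 ± 2.89 to 0.784 ± 0.192. WNT7B, a secreted Wnt ligand, fell from 20.4 ± 1.51 to 1.81 ± 0.185 CPM, and RNF43, a ubiquitin ligase that restrains Wnt receptors, from 11.9 ± 2.66 to 1.32 ± 0.603. The tetraspanin gene TSPAN15 fell from 8.83 ± 1.17 to 0.667 ± 0.388 CPM, the tyrosine kinase gene MATK from 7.71 ± 1.497 to 0.742 ± 0.263, and the zinc finger gene ZNF488 from 9.28 ± 0.812 to 0.967 ± 0.268. PAGR1, a subunit of the MLL3/MLL4 histone H3 lysine 4 methyltransferase complexes, fell from 32.5 ± 1.11 to 3.11 ± 0.861 CPM (-3.38 ± 0.20, edgeR adjusted p = 6.24e-05). The 3' UTRs of WNT7B, PAGR1 and ZNF488 held the 7 bases ACACCTG. In the annotation used here, 66.0% of the exonic bases of PAGR1 and 58.5% of those of RNF43 also belong to exons of another gene model, and 16.6% of those of RNF43 lie opposite exons of a further one, so their reads may have been divided between models.

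ASH2L, a core subunit shared by the H3K4 methyltransferase complexes, fell from 27.3 ± 0.867 to 12.9 ± 0.862 CPM (log2 fold change -1.08 ± 0.11, edgeR adjusted p = 0.000332), and its 3' UTR held ACACCTG followed by A. Of the 16 subunits of MLL/SET1 complexes, 4 fell, 1 rose and 11 did not pass the test, with the same counts when adjusted over the list alone. The other called members were CXXC1 at -0.45, PAXIP1 at -0.54 and KDM6A at 0.64, named here after their values were seen. The list was not called against all other genes (camera adjusted p = 0.137). The test fry called it down without a block (adjusted p = 0.0385) but not with the replicate block (adjusted p = 0.105).

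Most DNA replication genes fell. Of 45 genes of DNA replication and S phase, 37 fell, none rose and 8 did not pass the test (39 fell when adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 3.75e-14, adjusted p = 0.737 with an estimated correlation). The helicase subunit MCM5 fell from 126 ± 3.41 to 40.1 ± 3.05 CPM, the polymerase subunit POLA1 from 98.6 ± 10.2 to 38.5 ± 4.53, and the transcription factors E2F1 and E2F2 from 71.6 ± 3.21 to 26.3 ± 4.92 and from 14.4 ± 1.43 to 2.42 ± 0.671. Of 41 genes of mitosis and G2/M, 17 fell, none rose and 24 did not pass the test, with the same counts over the list alone (median -0.58, camera adjusted p = 0.000216, adjusted p = 0.797 with an estimated correlation). The mitosis list was not called by fry (adjusted p = 0.128). The DNA replication list was (fry adjusted p = 0.0197), but not with the replicate block (fry adjusted p = 0.0859). MYBL2, a transcription factor of the cell cycle, fell from 214 ± 12.8 to 39.8 ± 13.9 CPM and topoisomerase TOP2A from 268 ± 10.7 to 126 ± 42.01. CDC20, an activator of the anaphase-promoting complex, fell from 299 ± 25.9 to 133 ± 53.7, and BIRC5, which encodes survivin, from 177 ± 25.2 to 69.5 ± 29.2. The BIRC5 3' UTR held ACACCTG.

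Most NF-κB target genes rose. Of 31 tested, 19 rose, 1 fell and 11 did not pass the test (20 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 1.20 (camera adjusted p = 2.58e-08, adjusted p = 0.759 with an estimated correlation). The interleukin genes IL1A and IL1B rose from 5.85 ± 1.97 to 103 ± 34.6 CPM and from 3.96 ± 3.32 to 157 ± 32.1 CPM. PTGS2, the inducible prostaglandin synthase, rose from 8.62 ± 4.35 to 204 ± 114 CPM. The 1 lower gene was IRAK2, a kinase of the interleukin-1 receptor pathway, at -0.71, named here after its value was seen. The log2 fold change of IL1B was 5.32 with all libraries and 6.28 without shNT replicate 1, and that of CCL20 was 7.61 and 8.36.

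Among p53 target genes, 16 of 37 tested rose, 4 fell and 17 did not pass the test (18 rose and 4 fell when adjusted over the list alone). Their median log2 fold change was 0.39 (camera adjusted p = 0.00179, adjusted p = 0.737 with an estimated correlation). TP53INP1 rose from 1.14 ± 0.158 to 21.9 ± 6.80 CPM, although its 3' UTR held ACACCTG. The stress-induced SESN2 rose from 22.9 ± 3.39 to 71.04 ± 11.4 CPM, the cyclin gene CCNG1 from 96.4 ± 1.21 to 194 ± 24.5, and the death receptor gene TNFRSF10B from 159 ± 17.96 to 303 ± 11.99. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.65 on the log2 scale, and MDM2, a ubiquitin ligase, stood at 0.26 without passing the test (edgeR adjusted p = 0.0595). The 4 lower genes were FDXR (-1.16), KITLG (-0.81), AEN (-0.79) and CMBL (-0.64). These 4, CDKN1A and MDM2 are named here after their values were seen.

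Most mesenchymal genes rose and most epithelial genes tested fell. Of 30 mesenchymal genes, 20 rose, none fell and 10 did not pass the test (20 rose and 1, VIM at -0.37, fell when adjusted over the list alone), with a median log2 fold change of 1.06 (camera adjusted p = 1.13e-08, adjusted p = 0.0984 with an estimated correlation). Fibronectin (FN1) rose from 5038 ± 249 to 15244 ± 673 CPM and the matrix protein gene SPARC from 318 ± 9.53 to 1485 ± 212. The collagen gene COL5A1 rose from 265 ± 43.7 to 755 ± 10.4 CPM and LOX, which encodes the collagen cross-linking lysyl oxidase, from 202 ± 38.9 to 780.04 ± 127. Of the genes for mesenchymal transcription factors, ZEB2 at 0.80 and SNAI1 at 0.57 rose. ZEB1 at -0.22, SNAI2 at 0.33, TWIST1 at 0.12 and TWIST2 at -0.42 did not pass the test. These 6 and VIM are named here after their values were seen. Of 21 epithelial genes tested, 12 fell, 3 rose and 6 did not pass the test, with the same counts over the list alone (median -0.75, camera adjusted p = 0.000605, adjusted p = 0.608 with an estimated correlation). Keratin 7 (KRT7) fell from 716 ± 90.9 to 153 ± 2.49 CPM, the adhesion molecule gene EPCAM from 6.56 ± 0.767 to 1.02 ± 0.353 and the desmosomal plakophilin PKP3 from 14.6 ± 1.97 to 6.02 ± 0.556. The 3 that rose were the claudin CLDN1 at 2.05, CD24 at 1.32 and cingulin (CGN) at 0.81, named here after their values were seen. The number of the 30 mesenchymal genes above 1 CPM was 29 in shNT and 30 in shPHF20, and that of the 30 epithelial genes 20 and 17. The 3' UTR of SPARC held ACACCTG and that of COL5A1 held CACCTG followed by A, and 12.6% of the exonic bases of KRT7 lie opposite exons of another gene model.

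Of 36 lysosomal genes, 17 rose, 2 fell and 17 did not pass the test (19 rose and 2 fell when adjusted over the list alone), with a median log2 fold change of 0.33 (camera adjusted p = 0.00147, adjusted p = 0.793 with an estimated correlation). The sialidase NEU1 rose from 35.5 ± 2.83 to 76.7 ± 7.63 CPM, the proton pump subunit ATP6V1B2 from 73.9 ± 4.74 to 140.3 ± 8.77 and cathepsin B (CTSB) from 164 ± 10.8 to 343 ± 44.9. Against the list, the cholesterol-binding NPC2 fell from 68.6 ± 6.23 to 20.9 ± 1.23 CPM and cathepsin H (CTSH, named here after its value was seen) stood at -1.17. Of 34 genes of the autophagy machinery, 15 rose, 2 fell and 17 did not pass the test (18 rose and 2 fell over the list alone), with a median of 0.33 (camera adjusted p = 0.00611, adjusted p = 0.759 with an estimated correlation). The ATG8-family genes MAP1LC3B, MAP1LC3A and GABARAP rose from 168 ± 3.78 to 409 ± 61.3, from 5.10 ± 0.299 to 13.5 ± 1.52 and from 51.7 ± 2.34 to 106 ± 11.8 CPM. ATG4D, a protease that processes ATG8 proteins, fell from 30.6 ± 1.64 to 6.33 ± 0.180 CPM, and ATG2A, named here after its value was seen, stood at -0.42. The ATG4D 3' UTR held ACACCTG, that of CTSB held CACCTG followed by A, 17.5% of the exonic bases of ATG4D lie opposite exons of KRI1, and 30.5% of those of GABARAP belong to another gene model as well and 25.2% lie opposite a further one.

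Genes of the integrated stress response and amino acid supply rose in 22 of 34 cases, with 3 lower and 9 not past the test (24 rose and 4 fell when adjusted over the list alone, the fourth being SLC3A2 at -0.32). The median log2 fold change was 0.54 (camera adjusted p = 3.49e-05, adjusted p = 0.737 with an estimated correlation). The glutathione-degrading enzyme gene CHAC1 rose from 10.4 ± 1.41 to 26.995 ± 2.26 CPM, the stress-induced NUPR1 from 2.47 ± 0.459 to 12.8 ± 4.15 and VLDLR, a lipoprotein receptor gene whose 3' UTR held ACACCTG, from 11.1 ± 1.02 to 27.6 ± 1.97. The 3 lower genes were the leucine transporter SLC7A5 at -0.79, asparagine synthetase (ASNS) at -0.63 and the serine hydroxymethyltransferase SHMT2 at -0.50. They, SLC3A2 and ATF4 are named here after their values were seen. ATF4, whose protein drives this response, did not pass the test at 0.01.

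Most NRF2 target genes fell. Of 29 tested, 18 fell, 1 rose and 10 did not pass the test (19 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.49 (camera adjusted p = 5.40e-05, adjusted p = 0.608 with an estimated correlation). The pentose phosphate enzyme PGD fell from 484 ± 39.7 to 234 ± 12.5 CPM. GCLM, the modifier subunit of the glutathione-producing ligase, fell from 169 ± 11.5 to 88.3 ± 7.81 CPM, and its 3' UTR held ACACCTG. The nuclear receptor gene NR0B1 fell from 42.3 ± 2.35 to 20.5 ± 2.45 CPM. The 1 that rose was the epoxide hydrolase EPHX1 at 0.48, named here after its value was seen.

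**Figure D3:**
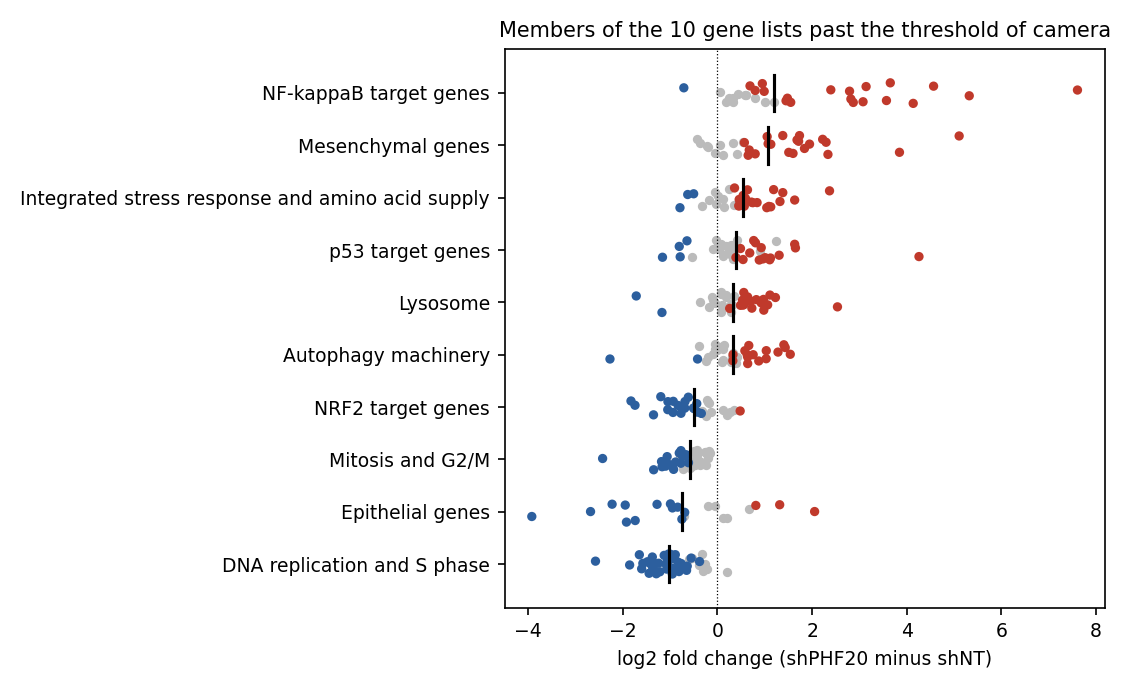
Each point is a tested member of a gene list past the threshold of camera, with the log2 fold change of shPHF20 minus shNT on the x axis. Red points rose, blue points fell and grey points did not pass the edgeR test, and black bars mark the list medians, which run from -1.01 for DNA replication to 1.20 for NF-κB targets.

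Oxidative phosphorylation and ribosomal protein genes moved little. Of 56 nuclear-encoded genes of oxidative phosphorylation, 12 fell, none rose and 44 did not pass the test (11 fell over the list alone), with a median log2 fold change of -0.19 (camera adjusted p = 0.0696). UQCRC1 of complex III fell from 221 ± 14.8 to 131 ± 6.23 CPM and SDHA of complex II from 265 ± 17.04 to 162 ± 17.8. Of 70 cytosolic ribosomal protein genes, 12 rose, 3 fell and 55 did not pass the test (2 rose and 2 fell over the list alone), with a median of 0.22 (camera adjusted p = 0.0594). RPS27 rose from 502 ± 24.7 to 742 ± 60.8 CPM and RPL31 fell from 515 ± 13.3 to 298 ± 21.98, both with many processed pseudogenes that can share their reads. With the replicate number as a block, both lists were called (camera adjusted p = 0.0254 for oxidative phosphorylation and 0.0251 for ribosomal proteins), but not with an estimated correlation as well (adjusted p = 0.800 for each in that paired fit). That setting called no list at all in the paired fit (lowest camera adjusted p = 0.760). Few residual degrees of freedom are left there, so it cannot decide about either list. Over the 16 refits of the list tests, the adjusted p ran from 0.00273 to 0.326 for oxidative phosphorylation and from 0.00436 to 0.354 for ribosomal proteins.

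Interferon-stimulated genes were divided, with 13 of 36 higher, 4 lower and 19 not past the test, counts that were the same over the list alone (median log2 fold change 0.34, camera adjusted p = 0.362). IRF9 rose from 5.97 ± 0.356 to 13.7 ± 1.21 CPM, with 93.5% of its exonic bases shared with another gene model, and IFI44L fell from 28.7 ± 3.95 to 11.3 ± 0.706. Of 16 MHC class I antigen presentation genes, 3 rose, 1 fell and 12 did not pass the test (2 rose and 1 fell over the list alone, camera adjusted p = 0.444). Beta-2-microglobulin (B2M) rose from 854 ± 199 to 2026 ± 583 CPM, and HLA-B rose from 32.5 ± 13.9 to 115 ± 68.3. HLA-B shares sequence with other HLA genes, 23.5% of its exonic bases lie opposite exons of a pseudogene, its 3' UTR held CACCTG followed by A, and its log2 fold change was 1.82 with all libraries and 1.21 without shPHF20 replicate 3. The HLA-B call was lost with no expression filter (edgeR adjusted p = 0.0607, against 0.000264 to 0.0463 in the other refits).

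Lipid genes moved both ways. Of 24 genes of cholesterol synthesis and uptake, 9 rose, 3 fell and 12 did not pass the test, with the same counts over the list alone (median log2 fold change 0.29, camera adjusted p = 0.281). Lanosterol synthase (LSS) fell from 73.2 ± 7.76 to 25.8 ± 3.26 CPM and PMVK from 16.8 ± 1.43 to 8.001 ± 0.222. Of 15 fatty acid synthesis genes, 1 rose, 2 fell and 12 did not pass the test (2 fell and none rose over the list alone, camera adjusted p = 0.515). Their median was 0.04 and their mean -0.13, with camera's direction down. The elongase ELOVL1 fell from 116 ± 8.43 to 23.9 ± 3.56 CPM, and the carboxylase ACACA stood at 109 ± 3.59 and 77.5 ± 12.2 CPM. The call of ACACA (log2 fold change -0.48, edgeR adjusted p = 0.0172) was lost without shNT replicate 1, 2 or 3, with an adjusted p of up to 0.0587. The 3' UTR of ELOVL1 held ACACCTG, and that of LSS held CACCTG followed by A.

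Of 31 cell death regulators tested, 12 rose, 6 fell and 13 did not pass the test (13 rose and 6 fell over the list alone, median log2 fold change 0.33, camera adjusted p = 0.111). BOK, a BCL2-family gene whose 3' UTR held ACACCTG, fell from 16.03 ± 0.635 to 1.98 ± 0.657 CPM. Of 36 hypoxia and glycolysis genes, 12 rose, 5 fell and 19 did not pass the test (13 rose and 5 fell over the list alone, camera adjusted p = 0.281). The demethylase KDM3A rose from 79.5 ± 6.18 to 145 ± 16.4 CPM and the phosphofructokinase PFKP fell from 469.8 ± 34.1 to 250.3 ± 31.1. Of 22 endoplasmic reticulum chaperone genes, 5 fell, 3 rose and 14 did not pass the test (the same over the list alone, camera adjusted p = 0.381). XBP1 fell from 148 ± 17.9 to 64.5 ± 6.06 CPM and MANF from 90.2 ± 14.9 to 32.7 ± 4.08, and their 3' UTRs held ACACCTG and CACCTG followed by A. Of 19 cytosolic heat shock genes, 4 rose, 6 fell and 9 did not pass the test (5 rose and 7 fell over the list alone, camera adjusted p = 0.864). DNAJB4 rose from 27.8 ± 1.79 to 57.3 ± 8.75 CPM and HSPA4 from 186 ± 11.5 to 294 ± 17.9.

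Signalling outputs were divided too. Of 25 MAPK output genes, 8 rose, 5 fell and 12 did not pass the test (the same over the list alone, camera adjusted p = 0.666), with the receptor gene EPHA2 falling from 112 ± 1.53 to 43.3 ± 8.08 CPM and ETV5, whose 3' UTR held CACCTG followed by A, from 69.2 ± 4.99 to 38.7 ± 2.61. Of 24 YAP/TEAD targets, 7 rose, 2 fell and 15 did not pass the test (the same over the list alone, camera adjusted p = 0.178). The growth factor TGFB2, whose 3' UTR held ACACCTG, rose from 77.2 ± 8.76 to 180.4 ± 19.3 CPM and ARHGEF17 from 36.3 ± 2.80 to 72.3 ± 8.30. Both values are uncertain, as 27.1% of the exonic bases of TGFB2 are shared with TGFB2-OT1 and 11.4% of those of ARHGEF17 lie opposite exons of another gene model. Of 18 TGF-β response genes, 7 rose, 3 fell and 8 did not pass the test (the same over the list alone, camera adjusted p = 0.236). The actin-binding TAGLN rose from 1.46 ± 0.249 to 8.10 ± 2.24 CPM, with 18.4% of its exonic bases opposite exons of PCSK7, and BAMBI rose from 26.7 ± 3.88 to 61.4 ± 14.2. Of 22 immediate early genes, 11 rose, 2 fell and 9 did not pass the test (the same over the list alone, camera adjusted p = 0.0696), with FOSB rising from 11.6 ± 1.03 to 25.4 ± 3.42 CPM and MCL1 from 234 ± 17.2 to 373 ± 23.4.

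Marker genes of other cells were few above 1 CPM, and they moved both ways. Of 29 myeloid leukaemia markers, listed because the protocol text names leukaemia lines, 11 could be tested. Of these, 4 rose, 4 fell and 3 did not pass the test (the same over the list alone, camera adjusted p = 0.717), and 7 were above 1 CPM in shNT and 6 in shPHF20. Their median log2 fold change was 0.46 and their mean -0.11, with camera's direction up. LAPTM5 rose from 5.92 ± 0.104 to 26.5 ± 5.87 CPM and MYB fell from 4.15 ± 1.06 to 0.700 ± 0.185. Of 12 endothelial markers 5 could be tested, of which 2 rose and 3 did not pass the test, and 1 was above 1 CPM in shNT and 2 in shPHF20 (the same over the list alone, camera adjusted p = 0.213). KDR rose from 0.435 ± 0.0924 to 4.58 ± 1.55 CPM and PECAM1, whose 3' UTR held CACCTG followed by A, from 1.10 ± 0.269 to 2.71 ± 0.221. Of 26 lung lineage genes 7 could be tested, of which 2 fell and 5 did not pass the test, and 5 were above 1 CPM in shNT and 6 in shPHF20 (the same over the list alone, camera adjusted p = 0.435). CAV1 fell from 496 ± 80.1 to 167 ± 44.7 CPM, and ABCA3 stood at 120.2 ± 33.7 and 73.6 ± 15.998 CPM (log2 fold change -0.71, edgeR adjusted p = 0.0341). The ABCA3 call was lost without shNT replicate 1 or 3 (adjusted p = 0.0833 and 0.111) and without shPHF20 replicate 1 or 2 (adjusted p = 0.111 and 0.0995), against 0.000203 to 0.0417 in the other refits. Of 13 replication-dependent histone genes tested, whose mRNA normally lacks a poly(A) tail, 5 rose, 2 fell and 6 did not pass the test (6 rose and 2 fell over the list alone, camera adjusted p = 0.213). HIST2H2BE rose from 11.5 ± 1.93 to 40.1 ± 10.2 CPM and HIST1H2BD from 14.2 ± 3.36 to 36.3 ± 7.28, and these genes share sequence with other histone genes.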

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

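The GC and length correction, its combination with the replicate block, and the fit without genes with a 3' UTR site were chosen after the data were seen. PHF20 stayed past the threshold in the 18 refits that tested it, with log2 fold changes from -2.18 to -2.03. It was left out by construction in the fit without site genes. Genes called numbered 6103 and, with the replicate block (paired), 8493, of which 6098 were among the 6103. They numbered 8441 with both the block and the GC and length correction, 5728 to 6570 over the other settings with all libraries and no block, 4762 without site genes, and 4578 (without shNT replicate 1) to 5898 (without shPHF20 replicate 3) without 1 library. In these 19 refits no gene called in both changed direction. The test against a fold of 1.5, which asks for more by construction, called 1873. The block changed no call among the named genes. With camera's preset correlation it changed none among the lists other than oxidative phosphorylation and ribosomal proteins, and with fry it ended 10 of 13 list calls and added 3. Since fry has fewer residual degrees of freedom with the block, its lost calls cannot be put down to the pairing itself. The 10 lists called stayed called in 16 refits with camera's preset correlation, where 10 to 13 lists were called. Among lists not called, ribosomal proteins gained a call in 8 of the 16, oxidative phosphorylation in 7, immediate early genes in 3, and MLL/SET1 subunits, histone genes and cell death regulators in 1 each. List tests were not run with DESeq2 or the GC and length correction. With an estimated correlation 0 lists were called. Over the lists called with the preset of 0.01, the estimate ran from 0.00759 (mesenchymal genes) to 0.870 (mitosis and G2/M). For the mesenchymal genes camera's unadjusted p still rose from 7.27e-10 to 0.00317, so a higher correlation does not account for the loss there. An estimated correlation also moves camera from the degrees of freedom of the genes to the fewer residual ones of the libraries. That by itself raises p, so the lost calls cannot be read as the effect of correlation alone. For the other lists how much each contributed was not tested. Of 1840 refits of 98 called named genes, 1832 kept the call and 8, in HLA-B, ACACA and ABCA3, lost it. Most of these genes were picked for a large change or a small adjusted p, so few losses were likely in advance. Of all 6103 genes called, 73.0% (without shNT replicate 1) to 87.5% (without shPHF20 replicate 3) stayed called without 1 library. In the self-test 20.9% of 1.5-fold changes were recovered, so a gene not called may have changed by that much, and 8493 genes were called with the block.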

Other observations

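The tests of direct matches as the whole cause, of the reverse complement and of growth, the match classes, the matches per list and the comparison of lists between libraries 2 and 3 were chosen after the results were seen. The libraries numbered 2 and 3 differed in several gene lists when both groups were fitted with 1 common difference. With group as a term (n = 2 against 2), edgeR called 3121 genes, and 9 of 31 lists passed camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.856). With an estimated correlation camera tests on the residual degrees of freedom, of which this fit has very few. A result of 0 was therefore likely in advance and cannot decide about the 9 lists. Library 3 was lower for oxidative phosphorylation (median log2 difference -0.44, camera adjusted p = 1.29e-18), mitosis and G2/M (-0.38, 2.44e-12), ribosomal proteins (-0.22, 9.15e-12), DNA replication (-0.31, 1.40e-05) and cholesterol synthesis (-0.29, 6.12e-05). It was higher for interferon-stimulated genes (0.37, 2.10e-06), NF-κB targets (0.25, 4.72e-05), lysosome (0.21, 0.00849) and MHC class I genes (0.21, 0.0312).

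Genes fell more often the more complete the match to ACACCTG in the 3' UTR. That 7-mer was picked for its lowest z on these same fold changes. Lower values in genes with all 7 bases follow from that choice, and the excess below is not separate support. Of 334 genes with ACACCTG followed by A, 35.6% fell (mean log2 fold change -0.26 ± 0.05 SE), of 1598 with ACACCTG 28.2% (-0.12 ± 0.02), and of 852 with CACCTG followed by A 25.7% (-0.07 ± 0.03). Of 2320 with CACCTG alone 23.8% fell (0.01 ± 0.02), and of 7587 without it 20.4% (0.05 ± 0.01). Of the 2784 genes with a match of 7 bases or more, 788 fell. The number expected from genes without CACCTG depended on how they were matched, at 411 by 3' UTR length, 513 by 3' UTR length and GC and 568 unmatched, an excess of 13.1%, 9.54% and 7.62% of the 2887 genes searched that fell. The last 2 references were added after the first was seen. No list differed in its share of matches after adjustment (Fisher's exact test, two-sided, 31 lists, lowest adjusted p = 0.434), and 3 lists had an unadjusted p under 0.05, all with fewer matches.

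The share of tested genes changed was 41.7%, for which loss of PHF20, off-target pairing of the hairpin and technical trends were weighed. A GC and length trend is argued against, with 6357 genes called after its correction and 5988 of the same 14157 genes before. Whole-chromosome copy number differences as the main source are argued against by size. Chromosomes held 0.293% of the variance, and the largest median was 0.125 in size. That share lay near the highest of 1000 shuffles (0.302%), so a small difference between chromosomes is not excluded. ACACCTG had the lowest z of 15730 7-mers (-9.45, lowest of 100 shuffles -4.34) and occurs 2 times in the PHF20 transcript, where 4523 of the 15730 occur, while its reverse complement had -1.54, which argues against a DNA element read on both strands. This is consistent with off-target pairing of the hairpin as a hypothesis, but not as the whole cause by direct matches, since 42.6% of the genes without CACCTG were called. Loss of PHF20, indirect effects of matched genes such as PAGR1 and ASH2L, and a microRNA or protein binding the same bases stay open, as neither the hairpin's sequence nor a second hairpin was used here.

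Same-numbered libraries deviated together, with library 3 minus library 2 differences correlating at r = 0.673 across genes between the groups. GC content is argued against, with Spearman correlations of 0.108 in shNT and -0.0691 in shPHF20 across genes, and transcript length, at 0.256 and 0.336, stays open. Of 86 proliferation genes 77.9% were lower in library 3 than in library 2 of both groups, against 38.9% of 14157 genes, but this share was computed after their lists had been seen to be lower, so growth of the cultures stays open. Across genes the difference correlated with the blocked fold changes of the knockdown at r = 0.0606. Lists could still move alike. Of those called between libraries 3 and 2, ribosomal proteins and cholesterol synthesis had the opposite camera direction in the knockdown. The others, among them DNA replication, mitosis, NF-κB targets and lysosome, had the same direction, called there or not. What the numbers share was not tested, and no biological explanation is named by the design.

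Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, called 6103 genes, and the highest other called 0. These splits are too few for a share under 0.05. Every other split also mixes shPHF20 and shNT libraries in both parts. The difference between the groups then adds to the spread within parts, so few calls were likely in advance. Besides the real split, 3 others part all 3 same-numbered pairs, and the remaining 6 part 1 pair.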
